A study of Homo sapiens with 15 samples.

How the data were processed

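Chromatin immunoprecipitation with BG4, an antibody raised against DNA G-quadruplexes, followed by sequencing was done in K562, an established human leukaemia line grown asynchronously. There were 2 biological replicates, with 2 technical libraries in replicate 1 (1a and 1c) and 3 in replicate 2 (2a, 2b and 2c). The files used here were 1 peak list per library and 1 list of high-confidence regions for all libraries. The 2 K562 input libraries and the 8 whole genome bisulfite libraries of HaCaT keratinocytes (4 control and 4 treated with 10 uM entinostat for 48 h) were not analysed here.

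Peaks were called with MACS2 on the hg19 genome, per the submitters' processing notes. The aligner, the control library, the filters, the settings and the version of the peak caller were not given in the sources used here. Peaks were called per library and not on pooled reads, as the separate lists show. In the deposited peak lists the score was the whole part of 10 times the −log10 p. The deposited fold enrichment was the ratio of the signal at the summit to the local background as the authors' peak caller estimated it. The deposited −log10 p and −log10 q belonged to the summit of each peak, and the lowest −log10 p of each list lay between 5.00 and 5.05. These values were the authors' own and were used only to describe, rank or filter peaks within their own list. The high-confidence list was deposited as positions alone, with no value per region, and the rule behind it was not stated. The number of reads per library was not given in the sources used here, so the depth is unknown.

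Positions are given on hg19 (GRCh37), counted from 1. The mitochondrial chromosome was left out of all comparisons with the reference, because the lists reached base 16571 while the reference mitochondrial sequence had 16569 bases. Start sites were those of protein-coding transcripts of protein-coding genes in GENCODE release 44 mapped to GRCh37, and a promoter was the sequence within 1 kb of a start site on either side. CpG islands were merged windows of 200 bp with a GC share of at least 0.5 and an observed over expected CpG ratio of at least 0.6. A stricter island had windows of 500 bp, a GC share of at least 0.55 and a ratio of at least 0.65. A G4 motif was 4 runs of 3 or more G with loops of 1 to 7 bases on either strand, wholly inside the region. Regions were compared with 1000 sets of random regions of the same widths on the same chromosomes, free of assembly gaps. In a second comparison the random regions were also matched on GC content. There 6000 positions were drawn per region, and up to 60 with a GC content within 2 percentage points were kept. For 121 of the 8940 high-confidence regions no position came that close, and the closest was used. Permutation p-values were one-sided, and 0.000999 is the smallest that 1000 sets can give.

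Peak lists were compared by the Jaccard index, the bases shared by both lists over the bases covered by either. The mean index within biological replicates was compared with that between them by an exact permutation test over the 10 splits of the libraries into groups of 2 and 3, one-sided. Regions counted as shared when they overlapped by 1 base or more. Gene lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 17 lists. The stratified form was an exact conditional test over the strata. Log2 odds ratios had a small constant added to each count, smaller within strata. For a list with no gene with a region the constant and the list size largely set that value. Shares have 95% Wilson intervals, differences of shares Newcombe intervals, and ratios of observed to expected regions per chromosome exact binomial intervals. These intervals cover counting error only, and neighbouring regions or genes of a cluster are not independent. Technical libraries were averaged within a biological replicate first, so values with an SD have n = 2.

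The genes named were fixed by a rule. It took the 10 protein-coding genes with a high-confidence promoter region, present in all 5 libraries, with the highest lowest percentile of fold enrichment over the libraries. From each gene list it took up to 4 members with the best ranked region and the first 2 members in alphabetical order without one. A gene outside that rule is named as such, and some genes that the rule took are not used here. The 17 gene lists covered textbook promoter quadruplexes, DNA methylation machinery, erythroid and megakaryocytic genes, other cell types, housekeeping and ribosomal protein genes, gene families, imprinted and germline genes, and loci altered in K562. Of 16 keratinocyte symbols 15 were used, and of 23 imprinted symbols 21 were used, since the others matched no single protein-coding gene. The comparisons, the tests, the gene lists, this rule and the first set of alternatives were chosen before the data were examined. The alternatives included stricter peak thresholds, other overlap rules, other promoter, island and motif definitions, GC matching, strata of CpG islands, and leaving out each library. The wider set of alternatives added later is named with the sensitivity results.

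Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9. Indexing used samtools 1.23.1, and bedtools 2.31.1 gave the same 10 pairwise indices. The steps were tested on simulated data. The motif search differed from a separate search in 0 of 600 sequences, and the overlap rule recovered 1200 of 1200 planted regions. A set of 400 regions with 50% planted at start sites was measured at 50.8%. Among 100 sets of random regions, 6 had p under 0.05 for promoters, 6 for CpG islands and 2 for G4 motifs. With promoters hit at random, 4 of 100 draws had a gene list past the threshold. With hits set by CpG islands alone this rose to 100 of 100 without strata and was 3 of 100 with strata. A housekeeping list planted at a share of 75% was called in 65 of 100 draws, and a HOX list planted at 5% in 96 of 100.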

Results

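G-quadruplexes (G4s), stacked structures that guanine-rich DNA can fold into, were mapped in K562, a human chronic myelogenous leukaemia line with erythroid features. Chromatin was precipitated with the antibody BG4 and sequenced in 5 libraries from 2 biological replicates, 2 technical libraries in replicate 1 (1a and 1c) and 3 in replicate 2 (2a, 2b and 2c). The series addresses how quadruplexes relate to DNA methylation, per its title. The peak lists held 12495 peaks in library 1a, 10079 in 1c, 8059 in 2a, 9026 in 2b and 11111 in 2c. The names of the peaks in lists 2a and 2c carried each other's letter; the sample labels were followed, so a value given for 1 of these libraries may belong to the other. The high-confidence list held 8955 regions with a median width of 205 bp and covered 2024709 bp. Of these regions 15 lay on the mitochondrial chromosome, and the other 8940 entered the comparisons of location, sequence and genes. The number of reads behind each list is unknown.

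The first comparison asked where in the genome BG4 regions lay. Most sat at gene promoters, in CpG islands, the CpG-rich stretches that are mostly unmethylated at active genes. Of the 8940 regions, 6695 (74.9%, 95% interval 74.0 to 75.8) lay within 1 kb of a protein-coding start site. Random regions of the same width and chromosome did so in 2.89%, a 26.0-fold difference. A CpG island was met by 88.2% (87.5 to 88.8) against 10.2%, which was 8.69-fold, and a strict island of 500 bp by 83.3% (82.5 to 84.0) against 2.57%. Regions farther from these start sites were classed by their middle against protein-coding genes alone. Introns held 10.1% of all regions, sequence outside these genes 13.4% and other exons 1.60%. Within 1 kb of a start site of any gene or transcript type lay 81.0%, so some of the classed regions were at other start sites. Each of the 3 enrichments had a permutation p of 0.000999, the smallest that 1000 random sets can give. Against random regions of the same GC content the promoter share remained 2.11-fold higher (35.5% expected) and the CpG island share 1.32-fold higher (67.0% expected), each with a permutation p of 0.000999. The peaks of single libraries lay at promoters in 61.5% to 75.4% of cases, with a mean over biological replicates of 67.5% ± 8.19 (SD, n = 2).

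**Figure D1:**
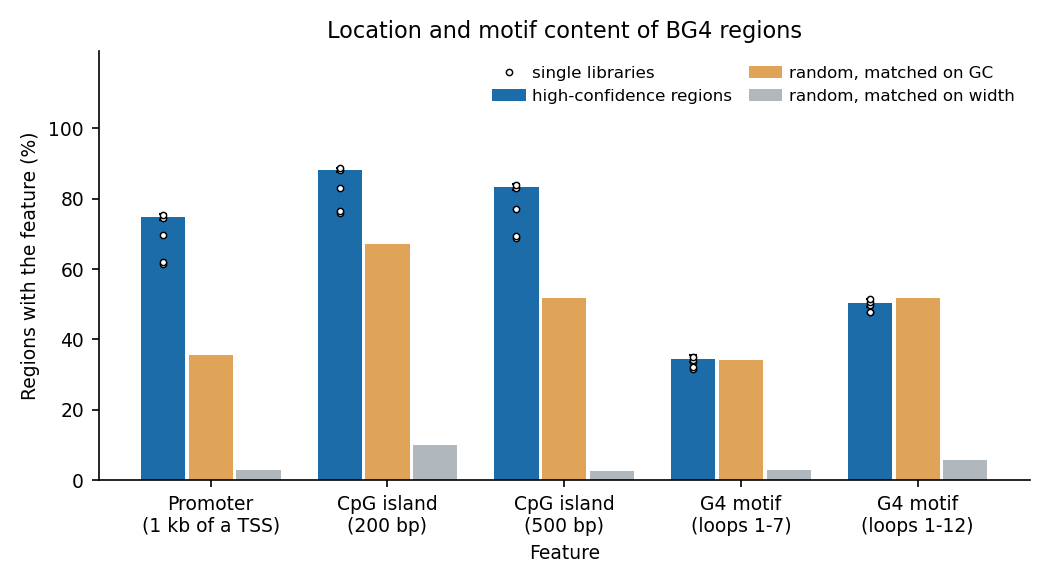
Share of regions (%) at promoters, in CpG islands of 2 definitions and holding a G4 motif of 2 definitions, for the high-confidence regions with 95% intervals and for random regions matched on GC or on width alone; points are single libraries. Promoters took 74.9% of the regions against 35.5% of the GC-matched and 2.89% of the width-matched regions, while G4 motifs were held by 34.5% against 34.2% and 3.04%.

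The promoters with the strongest BG4 peaks belonged to genes of varied function. Among them were CLIC4 (a chloride intracellular channel protein), ZNF7 (a zinc finger protein), SERGEF, KLF16 (a Krüppel-like transcription factor), TPRN, PLCD1 (a phospholipase C), BLVRB (biliverdin reductase B), SPTBN4 (a spectrin) and INPP5A (an inositol phosphatase). Each had a peak in all 5 libraries, with a fold enrichment in the top 2 percent of every list; the lowest percentile was 98.6. At CLIC4 (chromosome 1, 25071411 to 25071930, hg19) the region lay 8 bp upstream of a start site. It touched the annotated gene but none of the exons counted here. Fold enrichment at CLIC4 ran from 15.5 in library 2c to 20.9 in library 1a. At ZNF7 (chromosome 8, 146052556 to 146052991) it covered a start site and UTR, with folds from 14.2 to 21.9. At KLF16 (chromosome 19, 1863586 to 1864323) it had a GC content of 82.1% and folds from 14.4 to 19.2. BLVRB and SPTBN4 shared 1 region on chromosome 19 (40971571 to 40972115). The regions of CLIC4, ZNF7, SERGEF, KLF16 and INPP5A held a G4 motif, and those of TPRN, PLCD1, BLVRB and SPTBN4 did not.

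The second comparison asked how often BG4 regions held a sequence able to form a quadruplex. A canonical motif, 4 runs of at least 3 G with loops of 1 to 7 bases, was present in 3083 of 8940 regions (34.5%, 33.5 to 35.5). Random regions of the same width held it in 3.04%, an 11.3-fold difference with a permutation p of 0.000999, the smallest possible. Single libraries had a motif in 33.2% ± 0.858 of their peaks (SD, n = 2). The regions in all 5 libraries held it in 44.3%, which was 11.1 times the share in random regions of their own width and so no larger enrichment. Random regions matched on GC content held the motif in 34.2%, a ratio of 1.01 (permutation p = 0.223). With loops of up to 12 bases the share was 50.4% against 51.7% in GC-matched regions, whose lowest set had 50.3%. With runs of 2 or more G it was 91.7% against 93.7%, below the lowest GC-matched set (93.0%). The one-sided test does not count such shortfalls. Within 100 bp of the region's middle it was 33.8% against 31.7%, a 1.06-fold difference with a permutation p of 0.000999. There GC was matched over the whole region and not over that window, so a difference in the window's GC may enter.

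The third comparison asked which genes had a BG4 region at their promoter. Of 19785 protein-coding genes, 6795 (34.3%) did. The share was 45.1% among the 14800 genes with a strict CpG island within 1 kb of a start site and 2.51% among the 4985 without. Across 17 gene lists tested with Fisher's exact test and Benjamini-Hochberg adjustment, 3 had a region more often than other genes and 8 less often. A gene counted with a region at any of its start sites, and the number of start sites per gene was not controlled for. The 3 higher lists were housekeeping genes, ribosomal protein genes and the DNA methylation machinery. The 8 lower lists were markers of 3 other cell types (keratinocyte, hepatocyte and lymphocyte) and histone, HOX, clustered protocadherin, olfactory receptor and germline genes.

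Housekeeping genes had a region at 12 of 16 promoters (75.0%, log2 odds ratio 2.41, exact adjusted p = 0.00364) and were above other genes in 5 of 5 libraries. SDHA, a subunit of succinate dehydrogenase, TUBB, a tubulin, PGK1 of glycolysis and the actin gene ACTB were among them. The SDHA region (chromosome 5, 218150 to 218461) had folds from 10.1 to 15.1, while B2M had no peak in any library and GAPDH a peak in 2. The DNA methylation machinery had a region at 11 of 16 promoters (68.8%, log2 odds ratio 2.00, exact adjusted p = 0.0109), above other genes in 5 of 5 libraries. These included the maintenance methyltransferase DNMT1, its partner UHRF1, the de novo methyltransferase DNMT3B and the thymine glycosylase MBD4. The DNMT1 region (chromosome 19, 10305650 to 10305838) had folds from 5.49 to 8.84, and that of DNMT3B (chromosome 20, 31349974 to 31350208) from 7.08 to 10.5. DNMT3L had no peak in any library, and DNMT3A had a peak in 1. Ribosomal protein genes had a region at 41 of 81 promoters (50.6%, log2 odds ratio 0.97, exact adjusted p = 0.00695), above other genes in 5 of 5 libraries. RPS2, RPL18, RPL13 and RPL36 were among them, and RPL10L and RPL12 had no peak.

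**Figure D2:**
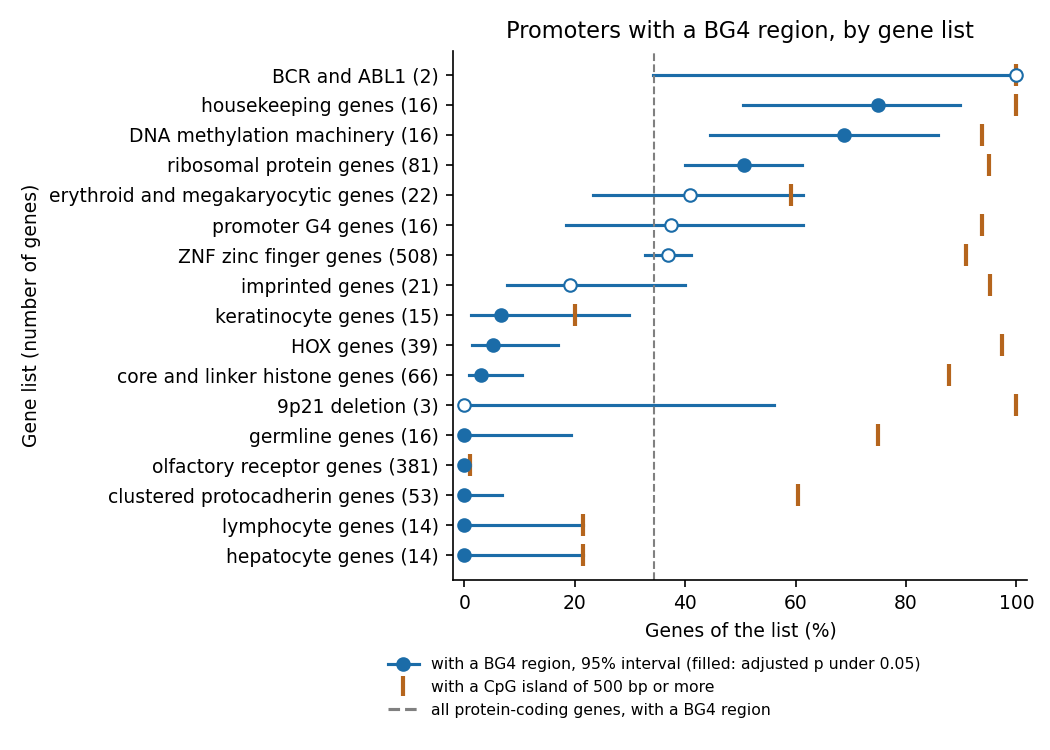
Genes of each list (%) with a high-confidence BG4 region within 1 kb of a start site, with 95% Wilson intervals, beside the share with a CpG island of 500 bp or more and the share of all protein-coding genes with a region (34.3%). Housekeeping genes reached 75.0%, while HOX genes stood at 5.13% and histone genes at 3.03%, although 97.4% and 87.9% of them had such an island.

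Among the lower lists, the replication-dependent core and linker histone genes had a region at 2 of 66 promoters (3.03%, log2 odds ratio −3.76, exact adjusted p = 4.14e-09). These were H2BC6, with a peak in all 5 libraries, and H1-4, with a peak in 3, while H1-1 and H1-2 had none. HOX genes, the developmental transcription factors of body patterning, had a region at 2 of 39 (5.13%, log2 odds ratio −2.98, exact adjusted p = 0.000109). These were HOXB9, in all 5 libraries, and HOXC13, in 3, while HOXA10 had no peak. Clustered protocadherin genes, which encode neuronal adhesion molecules and include PCDHA1 and PCDHA10, had 0 of 53 (interval up to 6.76%, exact adjusted p = 3.20e-09). Olfactory receptor genes, among them OR10A2 and OR10A3, had 0 of 381 (up to 0.998%, exact adjusted p = 7.21e-70). Germline genes such as BRDT and DAZL had 0 of 16 (up to 19.4%, exact adjusted p = 0.00640). Hepatocyte genes such as ALB and AHSG and lymphocyte genes such as CD2 each had 0 of 14 (up to 21.5%, exact adjusted p = 0.00695). Keratinocyte genes had 1 of 15 (6.67%, exact adjusted p = 0.0413), the region at SFN, while DSC3 and DSG1 had no peak. All 8 lists were below other genes in 5 of 5 libraries. Strict CpG islands were present at 87.9% of the histone promoters, 97.4% of the HOX promoters, 60.4% of the protocadherin promoters and 75.0% of the germline promoters, but at 1.05% of the olfactory receptor promoters.

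The erythroid and megakaryocytic genes of the K562 lineage had a region at 9 of 22 promoters (40.9%, log2 odds ratio 0.43, exact adjusted p = 0.576), which did not pass the test. Among them were the GATA1 cofactor ZFPM1 (chromosome 16, 88519090 to 88519749, folds from 10.9 to 19.7), LYL1, RUNX1 and the erythropoietin receptor EPOR, while ALAS2 and BCL11A had no peak. The textbook genes of promoter quadruplexes had a region at 6 of 16 (37.5%, log2 odds ratio 0.24, exact adjusted p = 0.796). HRAS, HIF1A and VEGFA were among them, and BCL2 and KIT had no peak in any library. The HRAS region (chromosome 11, 535544 to 535829) had folds from 8.20 to 13.1. ZNF genes had a region at 187 of 508 (36.8%, exact adjusted p = 0.288), with ZNF7, ZNF48 and the shared promoter of ZNF10 and ZNF891 the strongest. ZNF106 had no peak and ZNF100 had a peak in 2 libraries. Imprinted genes had 4 of 21 (exact adjusted p = 0.223), namely UBE3A, CDKN1C, PLAGL1 and L3MBTL1, but not DIRAS3 or DLK1. The 9p21 genes, a locus deleted in K562, had 0 of 3, CDKN2A and CDKN2B among them (exact adjusted p = 0.591), and no peak in any library. Both genes of the BCR-ABL1 fusion that drives this leukaemia had a region in all 5 libraries (2 of 2, exact adjusted p = 0.167).

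The gene list calls depended on how the regions and the comparison genes were chosen. With regions of all 5 libraries only, 5 of the 11 lists passed, namely housekeeping, histone, HOX, protocadherin and olfactory receptor genes. There ribosomal protein genes fell to a log2 odds ratio of 0.16. The DNA methylation machinery missed the threshold at 43.8% against 21.8% of other genes (exact adjusted p = 0.0942). Keratinocyte (−3.12), germline (−3.21), hepatocyte and lymphocyte genes (each −3.02) had 0 genes with a region. With 0 genes the constant added to each count largely sets these log2 odds ratios, so they do not measure an effect. Against genes of the same strict island class, 5 passed, namely histone, HOX, protocadherin, olfactory receptor and germline genes. There the adjusted p was 0.0609 for housekeeping (log2 odds ratio 1.86), 0.0708 for DNA methylation machinery (1.72), 0.229 for ribosomal protein (0.48), hepatocyte and lymphocyte genes (each −2.20), and 0.696 for keratinocyte genes (−0.51). Other classes kept some of these calls: within deciles of promoter GC ribosomal protein (log2 odds ratio 1.45, exact adjusted p = 0.000237) and housekeeping genes (exact adjusted p = 0.0444) passed, and within classes of the looser island housekeeping genes did (exact adjusted p = 0.0234). Without library 1c and with 3 of the other 4 libraries required, the adjusted p of the DNA methylation machinery was 0.0871 (log2 odds ratio 1.43). Keratinocyte genes had 0.0746 without library 2a (log2 odds ratio −2.19) and 0.0750 without 2b (−2.12), against a log2 odds ratio of −2.34 with all libraries.

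The fourth comparison asked how the regions were spread over the chromosomes. Chromosome 19, the most gene-dense, held 1009 regions, 5.78 times the number given by its length (95% interval 5.45 to 6.13). Chromosomes 17 (2.40), 22 (2.30), 16 (2.17) and 1 (1.52) followed. Chromosome 13 held 67 regions, 0.224 times the number given by length (0.174 to 0.284), and ratios were also low on chromosomes X (0.326), 4 (0.414) and 18 (0.428). Chromosome Y held 3 regions (0.0417). Of 24 chromosomes, 18 had an exact binomial interval that left out 1. Relative to the number of strict CpG islands the ratio was 1.44 on chromosome 19, 0.309 on chromosome 13 (0.240 to 0.392), 0.452 on X (0.384 to 0.529) and 0.561 on 18 (0.457 to 0.681). It was 1.18 on chromosome 17, 1.15 on 22, 1.26 on 16, 1.38 on 1, 0.655 on 4 and 0.0967 on Y, each nearer to 1 than the ratio by length. Relative to the looser CpG islands more of the excess on chromosome 19 remained, at 1.98 (1.87 to 2.10). By that count the ratio was 0.292 on chromosome 13, 0.421 on X and 0.523 on 18. K562 is aneuploid, and the number of chromosome copies was not measured here. Low ratios, that on Y included, therefore cannot be told apart from fewer or missing copies, nor high ratios from more copies.

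**Figure D3:**
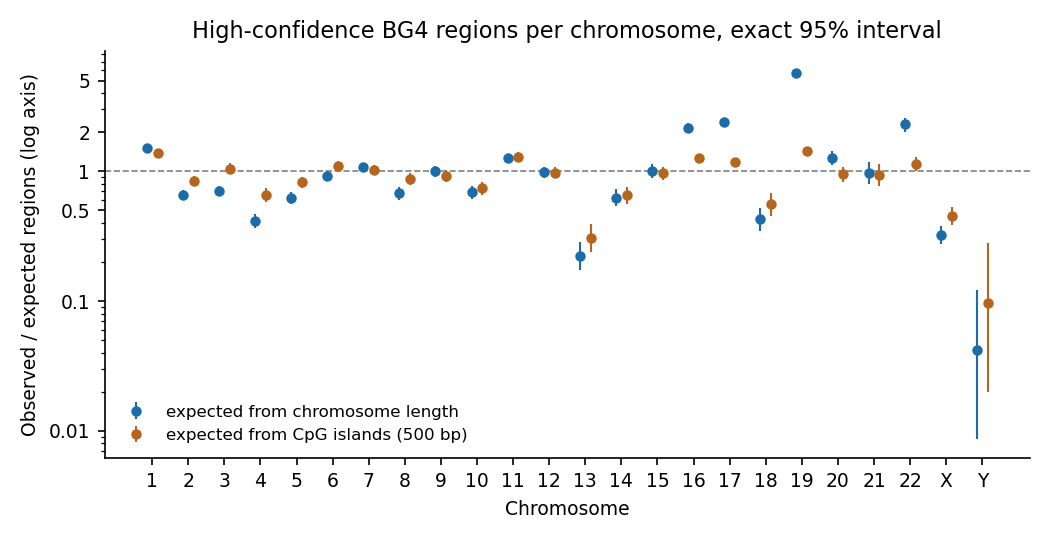
Observed over expected number of high-confidence regions per chromosome on a log axis, with the expectation from length and from strict CpG islands of 500 bp and 95% exact intervals. Chromosome 19 was highest by length (5.78), and chromosomes 13 (0.224), X (0.326) and Y (0.0417) were lowest.

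The fifth comparison asked how far the libraries shared their peaks. Libraries of replicate 1 had a mean of 11287 peaks and those of replicate 2 a mean of 9398.67, a ratio of 1.20. Peaks in the 5 libraries had median widths of 188 to 218 bp and median fold enrichments of 6.03 to 6.78. At −log10 p of 10 or more the mean over both replicates fell from 10342.8 to 6282. Pairs of libraries of the same biological replicate had a mean Jaccard index of 0.488, and pairs of different replicates 0.429. The difference of 0.0591 was the highest of the 10 possible splits, with 0.0246 the next, which gives an exact one-sided permutation p of 0.1, the smallest this design allows. It was 0.0384 with peaks of −log10 p of at least 10, where the next split had 0.0362, and 0.0365 without library 2a and 0.0307 without 2b. The pair 1a and 1c of replicate 1, at 0.437, lay below the pair 1a and 2c of different replicates, at 0.482. The 3 pairs of replicate 2 had 0.499 to 0.512.

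**Figure D4:**
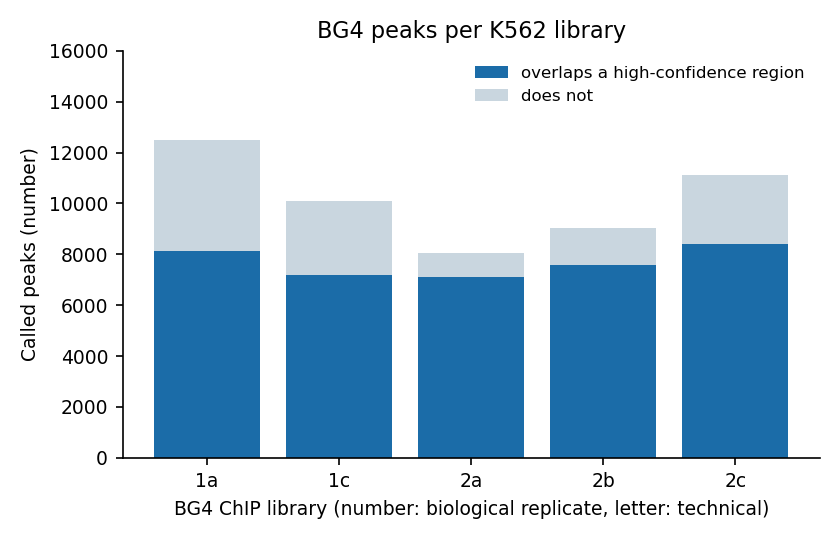
Number of called peaks in each of the 5 libraries, split into peaks that overlap a high-confidence region (dark) and peaks that do not (light). Peak numbers ran from 8059 in library 2a to 12495 in library 1a, and the share that overlapped a high-confidence region from 65.0% in 1a to 88.3% in 2a.

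The high-confidence regions were the stretches covered by at least 3 of the 5 libraries. The bases covered by 3 or more lists gave 8955 regions identical to the deposited ones. A peak was present in all 5 libraries at 4916 of them (54.9%, 53.9 to 55.9), in 4 at 1981 (22.1%) and in 3 at 2058 (23.0%). Both biological replicates contributed to 8703 (97.2%), and 252 (2.81%) rested on replicate 2 alone. No region can rest on replicate 1 alone under this rule. Without library 1a, 1697 regions rested on replicate 2 alone, and their share was 7.94% without 1c, 13.0% with peaks of −log10 p of at least 10, 11.6% with equal list lengths and 8.49% with a reciprocal overlap of 50%, and that of both replicates fell to as little as 71.4%. Of the 18219 regions with a peak in any library, 6964 (38.2%) had it in 1 library only. The share in all 5 libraries was 28.8% with peaks of −log10 p of at least 10.

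Peaks in the highest decile of fold enrichment were shared between libraries more than those in the lowest. In library 1a, 21.9% of the peaks in the lowest decile of fold enrichment and 99.8% of those in the highest were in the high-confidence list. In library 1c the shares were 29.5% and 99.8%, and in library 2a 75.0% and 99.9%. In replicate 2 the lowest decile was not the least shared. It had 59.1% against 52.4% in the next decile in library 2c, 74.7% against 71.2% in 2b and 75.0% against 73.7% in 2a. Stronger peaks were also wider, as given below, which makes an overlap of 1 base more likely. The difference between the highest and the lowest decile was 74.1 percentage points in replicate 1 and 29.8 in replicate 2, a mean of 52.0 ± 31.3 (SD, n = 2). It was positive in 5 of 5 libraries, from 24.3 to 77.8 points. The contrast between the replicates is set in part by the rule of at least 3 of the 5 libraries. A peak of replicate 2 can enter the list through its own replicate alone, and a peak of replicate 1 cannot. No test was made.

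**Figure D5:**
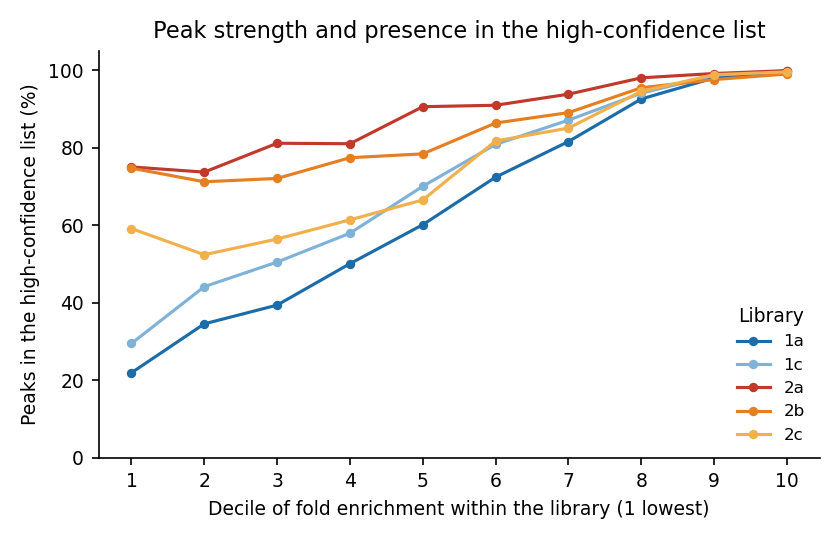
Share of each library's peaks in the high-confidence list (%) by decile of fold enrichment within that library, 1 line per library. The lowest decile ran from 21.9% in library 1a to 75.0% in library 2a, and the highest decile was at or above 99.0% in each.

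The sixth comparison asked whether what differed between the biological replicates differed in kind. A peak was present in both libraries of replicate 1 and none of replicate 2 at 617 regions, and in all 3 libraries of replicate 2 and none of replicate 1 at 231. The regions of replicate 1 alone lay at promoters in 32.5% of cases, against 76.2% of those of replicate 2 alone (Fisher's exact test, exact adjusted p = 5.00e-30 over 4 features). They met a CpG island in 50.2% against 89.6% (exact adjusted p = 1.07e-28), met a strict island in 38.8% against 81.8% and held a G4 motif in 20.8% against 37.2% (exact adjusted p = 2.12e-06). Their median GC content was 63.2% against 70.4%. Regions in all 5 libraries lay at promoters in 80.6% of cases. The counts moved with the rule: with libraries 2a and 2b alone standing for replicate 2 there were 1066 and 319 regions, and with 1c alone standing for replicate 1 there were 2493 and 867. With 1a alone there were 3393 and 407. With 1a alone or 1c alone standing for replicate 1 the promoter difference was −42.3 and −55.6 percentage points and the motif difference −22.6 and −24.6. With 2 libraries standing for each replicate the differences were smaller, from −28.8 (2a and 2c) to −34.9 percentage points (2b and 2c) for promoters against −43.7 with all 3, and from −7.88 (2a and 2b) to −12.4 (2a and 2c) for motifs against −16.5. The direction of the promoter difference was the same under each rule, and with 1 line and 2 biological replicates the values compare these libraries only.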

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

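No test was added for this part. The mitochondrial chromosome, which was left out of the comparisons of location, sequence and genes but not of those between libraries, held 15 high-confidence regions that together covered 13475 bases, more than the 3 regions set as the level for a closer look. Library 1a had 11 peaks there, 1c had 11, 2a had 15, 2b had 17 and 2c had 0. The median fold enrichment of these peaks was 2.72 in library 1a, 2.91 in 1c, 2.30 in 2a and 1.62 in 2b, against medians of 6.03 to 6.78 over all peaks of the libraries. Of 15 measures compared across the 5 libraries, 0 had a library past the critical gap for samples far from the others. The largest gap, that of library 2c in mitochondrial peaks, took 0.647 of the range. No explanation of the mitochondrial regions was tested.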

How the results depend on the processing

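Chosen after seeing the data were the GC-matched comparisons with other motif, promoter and island definitions, the strata of strict islands and of promoter GC, the restriction to regions of both biological replicates, strict islands as the basis for chromosomes, equal list lengths for the number of peaks and for the promoter difference, and leaving out libraries for peak numbers, strength, gene lists, chromosomes and replicate-specific regions; the other alternatives were chosen before. Of 133 alternative values of the main results, 103 kept their direction and side of the threshold or stayed near the main value. Near meant within its interval or SD or, for counts, within a fixed factor that was set by choice and is no measured spread. Of the other values 1 was no longer past the threshold, 27 moved and 2 reversed. Of 289 for single gene lists, 229 kept direction and side, 54 were no longer past the threshold and 6 reversed. Part of the kept values could hardly have come out otherwise, so these counts overstate the stability. Regions of at least 3 of the 5 libraries are the deposited list itself. The library permutation cannot pass the threshold, and peak strength was judged against an SD with n = 2. The cause was not tested unless given. No paired analysis was possible because the groups that share replicate numbers are the K562 input and ChIP libraries and the 2 groups of HaCaT libraries, and the input and HaCaT libraries were not analysed here.

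Against GC-matched regions the motif ratio was 1.01 (permutation p = 0.223), where GC is the matched property, with loops of up to 12 bases 0.974 and with runs of 2 or more G 0.979. For the high-confidence regions the promoter ratio stayed between 1.91 and 42.6 and the island ratio between 1.32 and 32.4 over the definitions and kinds of random region tried, with a permutation p of 0.000999 in each, the smallest possible. The mean number of peaks was 6282 at −log10 p of at least 10, which removes peaks by construction. The share of high-confidence regions in all 5 libraries was 28.8% at that threshold, 51.9% at −log10 q of at least 3, 44.2% with equal list lengths and 46.4% with a reciprocal overlap of 50%, each a stricter demand. It was 56.0% to 62.2% when a library was left out, where fewer libraries have to have a peak. Gene lists past the threshold numbered 5 with regions of all 5 libraries, 6 within CpG island classes, 5 within strict island classes, 7 within deciles of promoter GC, and 5 whichever library was left out with the other 4 all required, which leaves fewer regions. With 3 of the other 4 required they numbered 10 to 11. Textbook promoter quadruplex genes had a log2 odds ratio of −0.076 with 500 bp windows, −0.051 within island classes, −0.19 within strict island classes and −0.42 within GC deciles. For ZNF genes it was −0.17 and −0.28 within the 2 kinds of island class. Neither list passed the test in any setting. Regions of replicate 1 alone numbered 1066 with 2a and 2b as replicate 2, 410 at −log10 p of at least 10 and 2493 to 3393 when a library of replicate 1 was left out. Those of replicate 2 alone numbered 456 with 2a and 2c, 594 with 2b and 2c, and 407 to 867 when a library of replicate 1 was left out. Fewer libraries in the rule give more regions by construction. The permutation of libraries cannot give an exact p under 0.1, so it says nothing about the stability of the overlap. The unknown depth limits every statement about a missing peak.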

Other observations

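The spread of promoter regions over chromosomes, their relation to GC content, the motif content by peak strength, the region in POT1, the reading of GC content as a reason for the motif share and the cut to stronger peaks were chosen after the results were seen. Within genes with a strict promoter island, the share with a BG4 region was 22.1% (95% interval 17.5 to 27.5) on chromosome 13 and 21.9% (18.7 to 25.4) on X. The GC content of the same promoters gave 46.0% and 42.8%. Chromosome 14 had 34.0% (29.9 to 38.3) against 44.9%, and chromosome 18 36.5% (30.4 to 43.0) against 46.3%. The share was 58.2% on chromosome 16, 54.7% on chromosome 1 and 53.7% on chromosome 19. On chromosome Y it was 0 of 29 (up to 11.7%). Since K562 is aneuploid and chromosome copies were not measured, differences in copies may enter all these shares. By decile of promoter GC the share with a region was 0.101% in the lowest, 5.76% and 20.9% in the next ones, and between 43.3% and 49.7% from the fifth decile up.

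Strong peaks held a G4 motif more often in every library. In library 1a the share was 19.3% in the lowest of 4 equal groups of peaks by fold enrichment and 48.6% in the highest, and in library 2c 23.1% and 52.6%. The same peaks were wider, with medians of 171 and 323 bp in 1a and 167 and 312 bp in 2c, and richer in GC, with medians of 64.3% and 70.6% in 1a and 66.7% and 71.6% in 2c. Their promoter share rose as well, from 38.7% to 81.0% in 1a, so motif content rose together with width, GC content and location. A region in POT1, which encodes a telomere-protecting protein, stood apart by its sequence. It lay on chromosome 7 (124503375 to 124503900, hg19), met the coding exon at 124503404 to 124503694, had a GC content of 37.8%, held no motif and had folds of 6.68 to 8.45 in the 5 libraries. It was the 1 region under 45% GC among the 4916 in all 5 libraries, of which 3 were under 50%.

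The motif share of the high-confidence regions was like that of GC-matched regions, at 34.5% against 34.2% (ratio 1.01). Their GC content may account for the share, but this ratio is the pattern itself and no separate test of it. GC-matched regions were also free to overlap BG4 regions, which can bring the ratio nearer to 1. A trimming of the regions to the bases shared by 3 libraries is argued against, because regions at full width held the motif in 45.4% against 45.1% of their GC-matched regions, a ratio of 1.01 (0.984 to 1.03). That canonical motifs tell bound stretches of promoter islands from unbound islands beyond width and GC content is argued against as well. The 6407 regions in promoter islands held a motif in 37.6%. Windows of the same width and GC in 7133 promoter islands without any peak held it in 37.4%, a ratio of 1.01 (0.974 to 1.04). Whether islands with a motif are bound more often than islands without one was not tested. The match on GC takes out part of what makes a motif, and motifs beside the regions were not counted. Looser motifs gave ratios of 0.974 (loops of up to 12 bases) and 0.979 (runs of 2 or more G), a shortfall that the one-sided test does not count. Within 100 bp of the middle the ratio was 1.06 and for regions at full width 1.08 (each permutation p = 0.000999). That window was not itself matched on GC, so its GC content may account for these ratios. A small excess at the middle, a small shortfall of looser motifs and a contribution of open chromatin therefore stay open.

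The regions of replicate 1 alone lay at promoters less often than those of replicate 2 alone. With −log10 p of at least 10 the difference was −27.5 percentage points (−34.5 to −19.5), down from −43.7. At equal list lengths it was −27.8 points (−34.4 to −20.7). Both cuts also removed weaker peaks of the other replicate, so a region with such a peak there counted as alone. The cut lists thus compare other regions and cannot decide on weak peaks or longer lists as the whole reason. Lower GC content as the whole reason is argued against by a log2 odds ratio of −2.15 (−2.71 to −1.60) within GC quintiles against −2.73 without. Weak peaks, longer lists and GC content may each contribute a part, since the differences became smaller. Read depth and the condition of the cells in each replicate stay open, and no biological explanation was tested, because the design has 1 condition.

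Promoters of histone, HOX, clustered protocadherin and germline genes had few or no BG4 regions although most had CpG islands. Low GC content as the whole reason is argued against, because 4 of 4 lists had an adjusted p under 0.05 within deciles of promoter GC, with log2 odds ratios of −2.83, −3.59, −4.38 and −3.79 in that order. Protocadherin and germline genes had no gene with a region, where the GC deciles gave 6.69 and 4.36. Their odds ratios therefore rest on the constant added to each count. Loss of reads shared between near-identical copies is argued against for HOX genes. Each HOX promoter without a region had at least 96.4% of its 32-base words once in the genome. Over the 4 lists the median promoter had at least 89.8%. That share covers 1 kb on either side of a start site, so it can miss a repeated stretch as wide as a BG4 region (median 205 bp). For the other lists the loss of reads stays open. Only 45 of 64 histone and 11 of 16 germline promoters were above 80%, against 37 of 37 HOX and 45 of 53 protocadherin promoters. No biological explanation was tested, because expression, chromatin and methylation of these promoters were not analysed here.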
